A study of Homo sapiens with 6 samples.

How the data were processed

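H3K27ac, acetylation of lysine 27 of histone H3, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in 6 libraries of CCRF-CEM, an established human T lymphoblast leukemia line. Per the labels, parental cells and cells with a knockout of SLFN11 were each sampled after the vehicle DMSO and after 100 nM camptothecin for 2 h and for 4 h. The labels give 1 library per group, so no spread between replicates, standard error or p-value between groups was computed.

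The authors deposited 1 list of broad peaks per library, with coordinates on hg19. The submitters' processing notes name Trim Galore 0.6.2, Trimmomatic 0.39, BWA 0.7.17, SAMtools 1.8, Picard 2.9.2 and MACS2 2.1.2. Their settings are not given in the sources used here, and neither is whether the input or the IgG sample named in the labels' protocols served as the control of the peak calls. Since each library has its own list, peaks were called per library and not on pooled samples. The fold of a peak is the authors' ratio of pileup over the local background of that library. The −log10 p and −log10 q of a peak are the authors' deposited values, as MACS2 writes them. The deposited score is 10 times the −log10 q as a whole number, and it was used only to check that column. These values were used to describe, rank or filter peaks within a list. Reads, read counts and signal tracks were not analysed here.

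The lists differ in length, so comparisons used the 30000 peaks with the smallest p of each library on chromosomes 1 to 22 and X. Peaks on other sequences were left out of the comparisons. Overlap of at least 1 bp made a peak shared, and the value from 100 circular shifts of one list along each chromosome was set beside it. Wilson 95% intervals of shared percentages cover counting error over peaks only. The genome was tiled from position 1 into 10 kb windows, and a window was marked when a peak covered at least 1 bp of it. A window was gained when it was marked in the first library of a comparison and unmarked in the second, and lost in the opposite case. The signed difference between genotypes in the change of covered length, parental minus knockout, was counted where it reached 1000 bp in either direction.

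An annotation of hg19 was not used here, and the gene table at hand is placed on another build. The planned results on promoters, the SLFN11 promoter, exons and introns, gene bodies and the preset gene lists were therefore not run, and no gene is named at any coordinate. The rule set before the data were examined for this case named the 10 windows with the largest gain and the 10 with the largest loss of covered length, for parental 4 h against control, knockout 4 h against control and knockout control against parental control. Coordinates are 1-based.

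Sequencing depth was not in the lists. MACS2 computes the fold as the pileup plus 1 over the background plus 1, and p from the Poisson distribution, so the most frequent pair of fold and p in each list was solved for the pileup and the background. The background pileup in fragments per base returned the deposited −log10 p to within 1.22e-05 in all 6 lists. It serves as a measure of relative depth.

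A second comparison was chosen after seeing the data. Regions were made by merging the 15000 strongest peaks of the 5 libraries other than knockout 4 h, which gave 18835 regions with a median width of 1468 bp. Each region was ranked in each library by the smallest p of the deposited peaks in it, over the same set of regions. A region was called separated by a grouping when every library of one side ranked it above every library of the other by more than 3000 places. All 10 splits of the 5 libraries into 3 and 2 were counted in the same way. Intervals of medians over regions are 95% bootstrap intervals from 2000 resamples, and regions are not replicates of a group. For tests of depth and copy number on the genotype set, regions were picked by a rank gap above 3000 between parental 4 h and knockout 2 h alone, 3422 regions in all, and their shifts were measured in the other libraries. For the test of depth on the treated parental set, 1164 regions were picked by such a gap of both treated parental libraries to parental control. The median rank change from knockout control in those weaker after treatment, minus that in those stronger, was taken for knockout 2 h and 4 h.

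The steps were tested on simulated lists made from the parental control list. For windows marked in only one of 2 simulated libraries, all 200 emptied windows of 30286 were called lost and 0 were called gained. An emptied window is lost by definition, so this checks the code only. For regions separated between 3 and 2 simulated libraries, the −log10 p of 200 regions was changed. With a 1.5-fold change, 10% were recovered among 16572 regions. A 2-fold change gave 63% among 16573, and a 4-fold change 77% among 16610. Between 0 and 1 other regions were called at each size, and 0 of the changed regions were called on the wrong side. Apart from the changed regions, the simulated libraries shared all peak positions and differed only by random noise of a chosen size, without differences in depth. Real splits that follow neither genotype nor treatment separated 18 to 59 regions, so these low counts of other calls do not carry over.

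Alternatives were all deposited peaks, the 15000 or 60000 peaks with the smallest p, the 30000 peaks with the highest fold, peaks in order of p up to 50 Mb, peaks with a fold of at least 4, peaks with a −log10 q of at least 5, and larger overlaps. Windows of 5 and 20 kb, rank gaps of 2000 and 5000, regions from the 10000 strongest peaks, ranks by fold and the inclusion of the knockout 4 h library were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.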

Results

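H3K27ac, a histone mark found at active promoters and enhancers, was profiled by ChIP-seq in CCRF-CEM leukemia cells with and without SLFN11. SLFN11 is a protein of the Schlafen family known to sensitise cells to drugs that stall DNA replication. Camptothecin, an inhibitor of topoisomerase 1, was given at 100 nM for 2 h or 4 h, and DMSO was the control. Each of the 6 combinations of genotype and treatment had 1 library, so no difference below has a replicate check. The question set by the design was whether the marked chromatin changes after camptothecin, and whether it does so with and without SLFN11. The SLFN11 locus itself was not analysed here, so the knockout label was not checked. Positions are given on hg19 without gene annotation, and fold and p of peaks are the authors' values.

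The strongest peak of all 6 lists lay at one place, on chromosome 2 from 33141145 to 33141827 in parental control, with a fold between 12.8 and 13.3. Whether it is a mapping artifact was not checked, so it is uncertain as a marked site. Other strong peaks shared by all 6 libraries among their 100 strongest were on chromosome X from 123480248 to 123481156, with a fold of 9.83 in parental control, and on chromosome 12 from 11323631 to 11324444, with a fold of 10.4. The mark was densest on chromosome 19, with a mean of 23.7 peaks per Mb over the 5 libraries other than knockout 4 h, followed by chromosome 22 with 19.4 and chromosome 17 with 18.5. Chromosome 4 was the sparsest, with 6.87 peaks per Mb.

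The parental lists held 174843 peaks in control, 180754 at 2 h and 181577 at 4 h. The knockout lists held 271785 in control, 221753 at 2 h and 410176 at 4 h. The deposited peaks covered 126, 128 and 130 Mb in the parental libraries and 197, 162 and 194 Mb in the knockout libraries, in the same order. Outside knockout 4 h, strong peaks were more even in number. At a −log10 q of at least 5, parental control, 2 h and 4 h held 14309, 13140 and 13376 peaks, and knockout control and 2 h held 14961 and 15748. In the knockout 4 h list there were 5671 at that level and 1366 at a −log10 q of at least 10, where the other libraries held between 8553 and 10451.

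The libraries differed in background pileup, taken here as a measure of relative depth. The background pileup was 0.603 fragments per base in parental control, 0.506 at 2 h and 0.570 at 4 h. It was 0.699 in knockout control, 0.715 at 2 h and 0.168 at 4 h. At 4 h the knockout library thus had 0.241 times the background of its control. In its list, 59.7% of the peaks carried the single most frequent pair of fold and p, which stands for a pileup of 1 fragment, against 14.0% to 17.5% with a pileup of 2 in the other libraries. Its median peak width was 200 bp, the smallest width in any list, against 431 to 449 bp elsewhere.

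**Figure D1:**
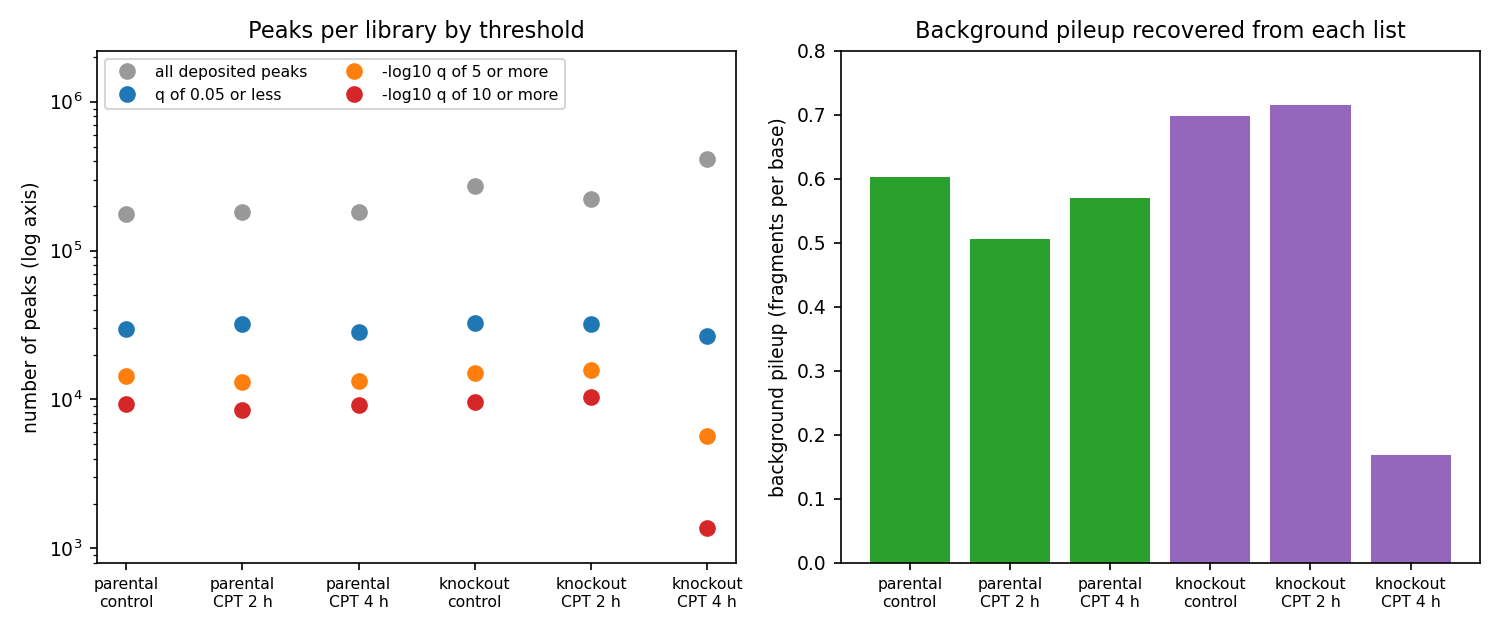
Left, the number of peaks per library (log axis) in the whole list and at 3 thresholds of q. Right, the background pileup of each library in fragments per base, with parental libraries in green and knockout libraries in purple. The knockout 4 h library has the most peaks (410176), the fewest at a −log10 q of 10 or more (1366) and the lowest background (0.168).

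Most strong sites were marked in every library. Of 18835 regions built from the strongest peaks of the 5 libraries other than knockout 4 h, 88.3% held one of the 30000 strongest peaks in all 5, and 73.4% in all 6. Every one of the 5000 strongest peaks of each of these 5 libraries overlapped a deposited peak in the others. Among the matched lists of 30000 peaks, 71.4% to 78.0% of peaks were shared in the 10 pairs without the knockout 4 h library, and 57.6% to 62.4% in the 5 pairs with it, over both directions. Circular shifts gave at most 3.08%. The pair that shared most was knockout control and knockout 2 h (77.8% of the control peaks, Wilson 95% interval 77.3 to 78.3). Parental control shared 71.6% of its peaks with parental 2 h (71.1 to 72.1), 73.9% with parental 4 h (73.4 to 74.4) and 75.3% with knockout control (74.8 to 75.8). The order of these 3 values depended on the peaks taken: with 50 Mb of peaks they were 64.9%, 64.6% and 63.1%, and with 15000 peaks 88.6%, 89.97% and 89.87%. Knockout control shared 60.0% of its peaks with knockout 4 h (59.4 to 60.6).

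**Figure D2:**
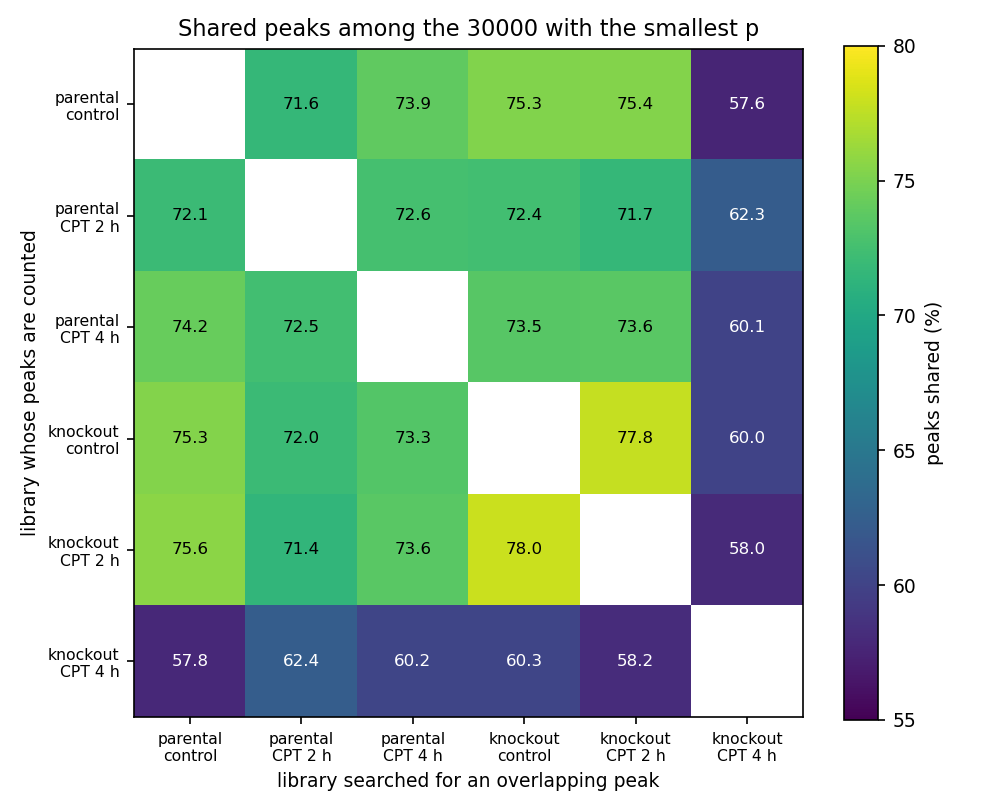
Percentage of the 30000 peaks with the smallest p of the library in each line that overlapped such a peak of the library in each column by at least 1 bp. Pairs without knockout 4 h lie between 71.4% and 78.0%, and pairs with it between 57.6% and 62.4%.

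After 2 h of camptothecin, 8092 of the 10 kb windows were marked in treated parental cells and not in the parental control, and 7785 the other way round, with 22501 marked in both. The balance depended on how peaks were chosen. With peaks of a −log10 q of at least 5 there were 815 gained and 2063 lost windows, with at least 500 bp covered 2745 and 4339, and with 50 Mb of peaks per library 22181 and 13119. The background pileup at 2 h was 0.839 times that of the control. Agreement was lower for weaker peaks. Of the parental control peaks ranked 1 to 5000, 100% were in the matched list at 2 h, against 68.4% of those ranked 15001 to 20000 and 33.3% of those ranked 20001 to 30000. Among all deposited peaks at 2 h, 95.5% and 84.5% of these 2 groups were found.

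After 4 h in parental cells, the largest gain of covered length lay on chromosome 1 from 228760001 to 228770000, where peaks covered 2478 bp in the control, 3265 bp at 2 h and the whole 10000 bp at 4 h. The peak that filled it was the widest of that list, 12358 bp long, with a low fold of 1.35 and rank 23868 by p. Whether this place belongs to the 5S ribosomal RNA repeat array, where reads map to many copies, was not checked without an annotation, so the gain is uncertain. The same window had 2324 bp in knockout control, 0 at 2 h and 4109 bp at 4 h. On chromosome 4, the window from 40230001 to 40240000 rose from 2211 bp to 5086 bp at 2 h and 6371 bp at 4 h, and in knockout cells it went from 2954 bp to 5151 bp at 2 h and 1138 bp at 4 h. The windows on chromosome 9 from 130710001 to 130720000, with 4181 bp, and on chromosome 6 from 43080001 to 43090000, with 3861 bp, were covered at 4 h and at 0 in control and at 2 h. Both also held peaks in knockout control, 2249 and 1771 bp long. On chromosomes 14 and 1, the windows starting at 23100001 and 10550001 were covered in parental 4 h (3378 and 3211 bp) and in no other matched list. Weaker peaks of the other libraries in these windows were not looked up. Of the 10 named gains, 3 also rose in knockout 2 h and 1 in knockout 4 h.

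The largest parental loss at 4 h was on chromosome 12 from 57420001 to 57430000, with 4945 bp in the control and 0 at both 2 h and 4 h. In knockout cells the same window held 4879 bp in control and 5040 bp at 2 h, and 0 at 4 h. Chromosome 14 from 91870001 to 91880000 followed the same course, from 4558 bp to 1237 and 0 in parental cells, and 5077, 4397 and 0 in knockout cells. On chromosome 5 from 133450001 to 133460000, cover was 8378 bp in parental control and 4033 and 4042 bp after treatment, while knockout cells had 8971, 8967 and 4045 bp. On chromosome 6, the window from 26240001 to 26250000 fell from 4886 bp to 837 and 875 bp in parental cells, and stood at 4244, 4267 and 888 bp in knockout cells. Other named losses also fell in the knockout: on chromosome X from 19880001 and chromosome 3 from 53200001, cover went from 1546 and 2066 bp in knockout control to 0 at both times. Of the 10 named losses, 5 were lower in knockout 2 h than in knockout control and 8 in knockout 4 h, and the other 2 had 0 in every knockout library. Among the 5, the chromosome 5 window went only from 8971 to 8967 bp. Knockout 4 h also had 0 in 7 of the 10 windows named as parental gains, so its low cover cannot be told from an effect of its low background. Values at 2 h and 4 h share the 1 parental control library by which these windows were picked, so their agreement is no independent evidence. Across all windows, 7342 were gained and 7187 lost. The balance again depended on the choice of peaks, with 843 and 1800 at a −log10 q of at least 5, 18457 and 13604 with 50 Mb of peaks, and 28413 and 26577 with all deposited peaks.

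**Figure D3:**
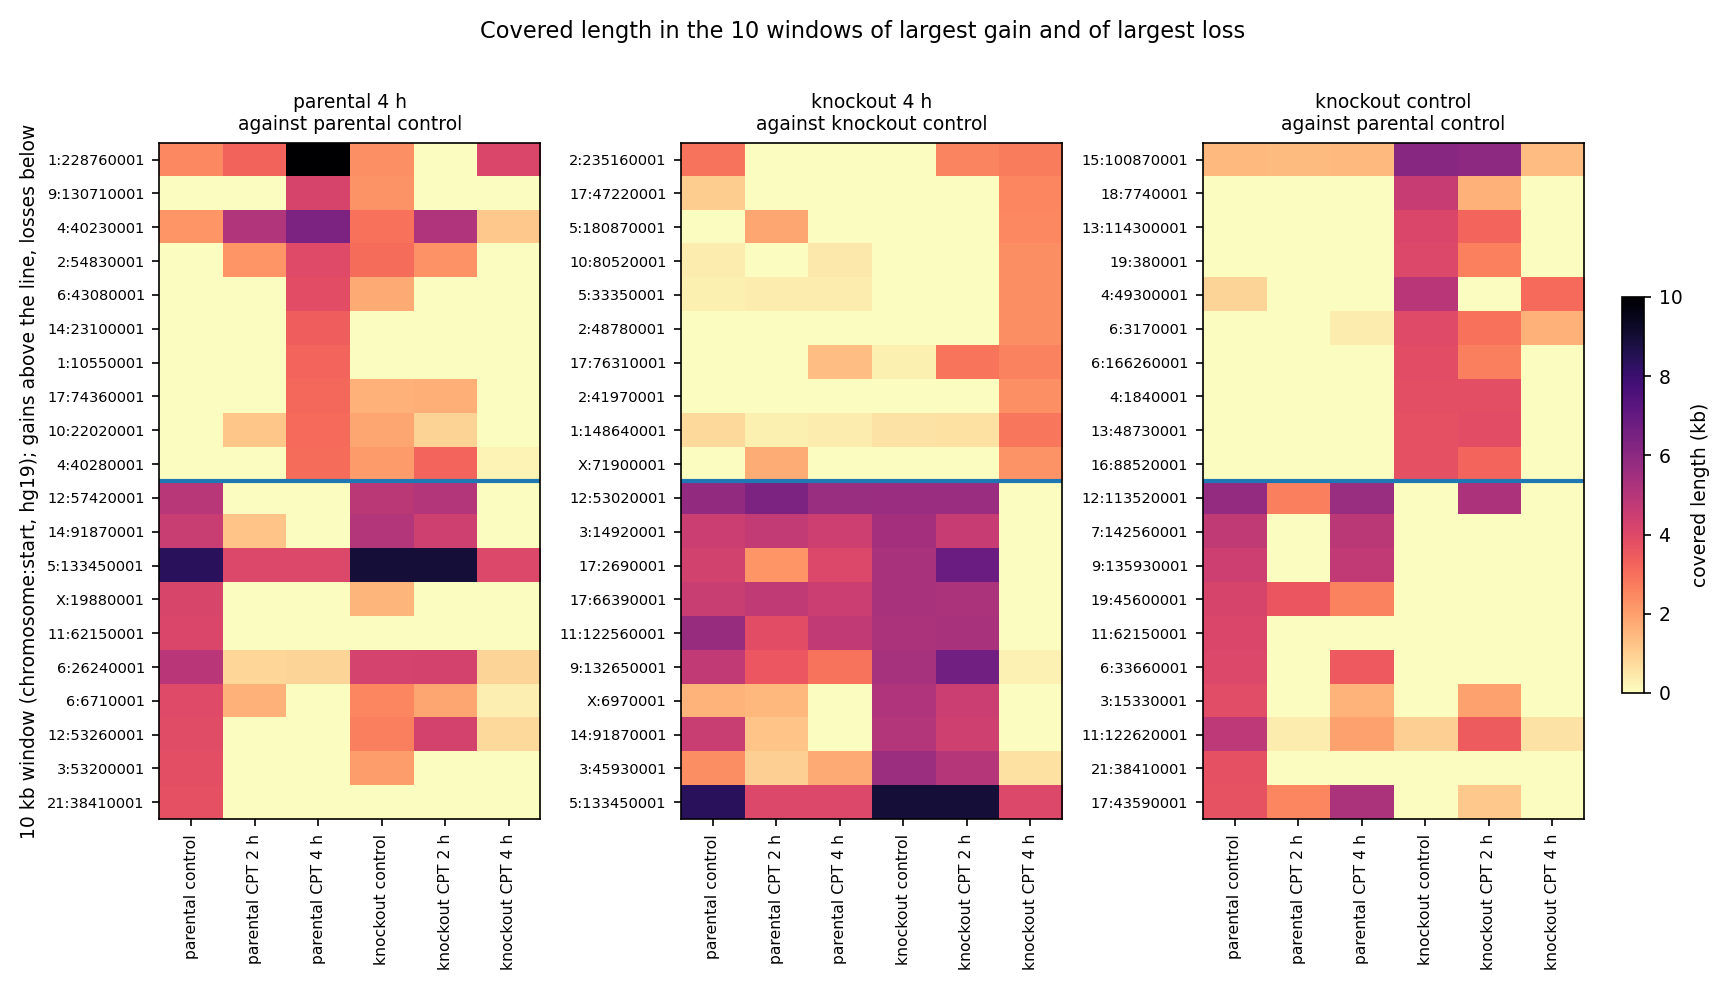
Length covered by peaks of the matched lists, in kb (colour), in each of the 6 libraries. Shown are the 10 windows with the largest gain (above the line) and the 10 with the largest loss (below it) in 3 comparisons. Windows named as losses of knockout 4 h are mostly covered in the other 5 libraries, for example 5653 bp in knockout control and 5673 bp in parental 4 h on chromosome 12 from 53020001.

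In knockout cells, 5965 windows were gained and 6252 lost after 2 h, with 23958 marked in both. With all deposited peaks, 18626 were gained and 43533 lost, and with a −log10 q of at least 5 there were 1613 and 896. After 4 h, 11546 were gained and 10795 lost. These numbers come with the low background pileup of that library (0.168), and other choices gave other balances: 65003 gained and 14623 lost with all peaks, 37061 and 13841 with 50 Mb of peaks, 3822 and 8169 with 500 bp covered, 2251 and 6641 at a fold of at least 4, and 269 and 9840 at a −log10 q of at least 5. The largest losses lay on chromosome 12 from 53020001 to 53030000, with 5653 bp in the control, and on chromosome 3 from 14920001 to 14930000, with 5426 bp. Both were at 0 in knockout 4 h and covered in all 5 other libraries. The largest gain was on chromosome 2 from 235160001 to 235170000, with 0 in knockout control, 2575 bp at 2 h and 2713 bp at 4 h, where parental cells went from 2908 bp in control to 0 at both times. On chromosome 17, the window from 47220001 to 47230000 held 2510 bp at 4 h and 1046 bp in parental control, and 0 in the other libraries.

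The change in the parental cells was set against that in the knockout. Changes were signed, so a smaller loss counts as the greater change. At 4 h, the signed change in covered length was greater in parental cells by at least 1000 bp in 6057 windows. It was greater in knockout cells in 2221. The mean change at 4 h was −40.8 bp in parental and −181.9 bp in knockout cells. Windows shorter than in control by at least 1000 bp numbered 2322 and 6115, so knockout 4 h lost more cover in the matched lists. With all deposited peaks on these chromosomes, cover was 193 Mb in knockout control and 190 Mb in knockout 4 h. The counts at 4 h cannot be told from an effect of the low background of knockout 4 h. At 2 h the order of the counts of greater change was the opposite, with 2213 and 4440 windows. The median difference was 0 bp at both times over 56591 windows. Among windows marked in only one of treated and control cells in both genotypes, 46.0% of 3951 went the same way at 2 h, and 61.5% of 5034 at 4 h. Without any relation the shares would have been 49.96% and 49.98%. At 4 h the treated libraries of both genotypes had a lower background than their controls (0.945 and 0.241 times), and at 2 h the parental library had a lower one (0.839 times) and the knockout library a higher one (1.02 times).

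Without treatment, the knockout differed from the parental cells by 6841 gained and 6917 lost windows, with 23369 marked in both. With all deposited peaks there were 57862 and 12416, and with a −log10 q of at least 5 there were 1805 and 1173. The largest gain in the knockout was on chromosome 15 from 100870001 to 100880000, with 1470 bp in parental control and 6114 bp in knockout control. It stood at 5963 bp in knockout 2 h, and at 1425 and 1463 bp in treated parental cells. In knockout 4 h the cover was 1396 bp. On chromosome 18 from 7740001 to 7750000, on chromosome 13 from 114300001 to 114310000 and on chromosome 4 from 1840001 to 1850000, knockout control had 4594, 4113 and 3812 bp and all 3 parental libraries had 0. Knockout 2 h had 1605, 3237 and 3802 bp in them, and knockout 4 h had 0. Of the 10 named gains, 9 were also higher in knockout 2 h than in parental 2 h. In knockout 4 h, with its low background, 2 were higher than in parental 4 h. Among the named losses, chromosome 19 from 45600001 to 45610000 was covered by 4202, 3619 and 2616 bp in the parental libraries and by 0 in all 3 knockout libraries. The largest loss, on chromosome 12 from 113520001 to 113530000, had 5788 bp in parental control and 0 in knockout control, but 5225 bp in knockout 2 h. Of the 10 named losses, 8 were lower in knockout 4 h than in parental 4 h, and 2 in knockout 2 h than in parental 2 h, where 5 were at 0 in both. The rest were higher in knockout 2 h than in parental 2 h. Their values were 5225 against 2688 bp on chromosome 12 from 113520001, 1945 against 0 on chromosome 3 from 15330001, and 3462 against 385 on chromosome 11 from 122620001. Knockout 4 h had 0 in 9 of the 10 named losses, which cannot be told from an effect of its low background. The windows on chromosome 11 from 62150001 and on chromosome 21 from 38410001 were covered in parental control and in no other matched list.

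Ranks over the fixed regions gave 435 regions (2.31%) that separated the 3 parental libraries from knockout control and 2 h, 309 stronger in the knockout and 126 stronger in the parental cells. With knockout 4 h included, 3 libraries against 3, these counts were 133 and 85. Single libraries against the other 4 all had more stronger than weaker regions, for example 545 and 106 in parental 2 h. The rule may thus favour the side with fewer libraries, so the excess is not read as a net gain. The regions named here are among the 10 with the widest rank gap in each set, a rule set after the data were seen. The separated regions were of middle to low strength, with a median mean rank of 13779 and 12774, against 9603 for all regions. The widest gap towards the knockout was on chromosome 19 from 16022370 to 16023167, which ranked 15920, 12761 and 15242 in parental control, 2 h and 4 h, and 793 and 267 in knockout control and 2 h. It ranked 1342 in knockout 4 h. The region on chromosome 12 from 26111071 to 26112435 ranked between 11446 and 13054 in parental cells and at 1625, 950 and 909 in knockout cells. On chromosome 3 from 18426648 to 18428218 the parental ranks were 14556, 16857 and 16830 and the knockout ranks 4178, 3234 and 5402. Towards the parental cells, the widest gap was on chromosome 14 from 105742183 to 105743983, with ranks of 2763, 4209 and 2618 in parental cells and 17953, 17676 and 13259 in the knockout. Chromosome 3 from 169529717 to 169530850 ranked 4306, 3681 and 4375 in parental cells and 14827, 16465 and 17877 in the knockout. For knockout 4 h, which was not used to choose the regions, the median rank was 12640 in those stronger in the knockout and 15697 in those stronger in parental cells, a difference of 3057 (95% interval 2262 to 3970).

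A smaller set of 161 regions (0.855%) separated both treated parental libraries from parental control, knockout control and knockout 2 h. Of these, 71 were stronger and 90 weaker in treated parental cells. With strength taken from fold, the set held 420 regions. The largest fall was on chromosome 3 from 17980562 to 17981525, from rank 6750 in parental control to 16075 at 2 h and 17511 at 4 h, with 1642 and 1211 in knockout control and 2 h and 2899 in knockout 4 h. On chromosome 15 from 56970017 to 56970794 the rank fell from 4085 to 9749 and 10162 in parental cells, and stood at 2872 and 4113 in knockout control and 2 h. Knockout 4 h ranked it at 13302. The rise with the widest gap was on chromosome 17 from 55002975 to 55003251, from rank 18401 to 11070 at 2 h and 12599 at 4 h. Knockout control, 2 h and 4 h ranked it at 18540, 18283 and 13086. Another named region that rose was on chromosome 20 from 34203503 to 34205780, from rank 9311 to 2277 at 2 h and 4523 at 4 h. It ranked 10825, 10007 and 8343 in knockout control, 2 h and 4 h. The region on chromosome 19 from 57018959 to 57019786 went from rank 13954 to 9128 and 7727 in parental cells and ranked 18314, 18611 and 18716 in the knockout. In regions that rose, the median rank was 17247 in knockout control, 16599 at 2 h and 13061 at 4 h. In regions that fell it was 10040, 10165 and 13297. Only knockout 4 h was not used to choose these regions. In 1164 regions chosen by parental libraries alone, the knockout ranks also moved towards treated parental cells. From control to 2 h the median change was 332 in the weaker and −275 in the stronger regions, a difference of 607 (95% interval 425 to 932). From control to 4 h it was 1247 and −1405, a difference of 2652 (2073 to 3213), with the low background of that library.

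Camptothecin in both genotypes, taken as parental 2 h and 4 h and knockout 2 h against both controls, separated 59 regions, 12 stronger and 47 weaker after treatment. The largest fall was on chromosome 3 from 18027838 to 18028202, from ranks 10443 and 10689 in parental and knockout control to 18792 and 16447 in treated parental cells and 16314 in knockout 2 h. Chromosome 1 from 200123525 to 200124030 went from 8637 and 7557 to 14247, 16297 and 17472 in the same libraries. Knockout 4 h, with its low background and not used in the choice, ranked these falls at 17518 and 18254. The largest rise was on chromosome 1 from 206290121 to 206290511, from 15454 and 16188 to 8596, 9536 and 8743, with 15792 in knockout 4 h. The 7 splits of the 5 libraries that follow neither genotype nor treatment separated 18 to 59 regions each, so the count for camptothecin in both genotypes did not exceed them. Single libraries set against the other 4 separated 252 to 651 regions, with the most for parental 2 h.

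**Figure D4:**
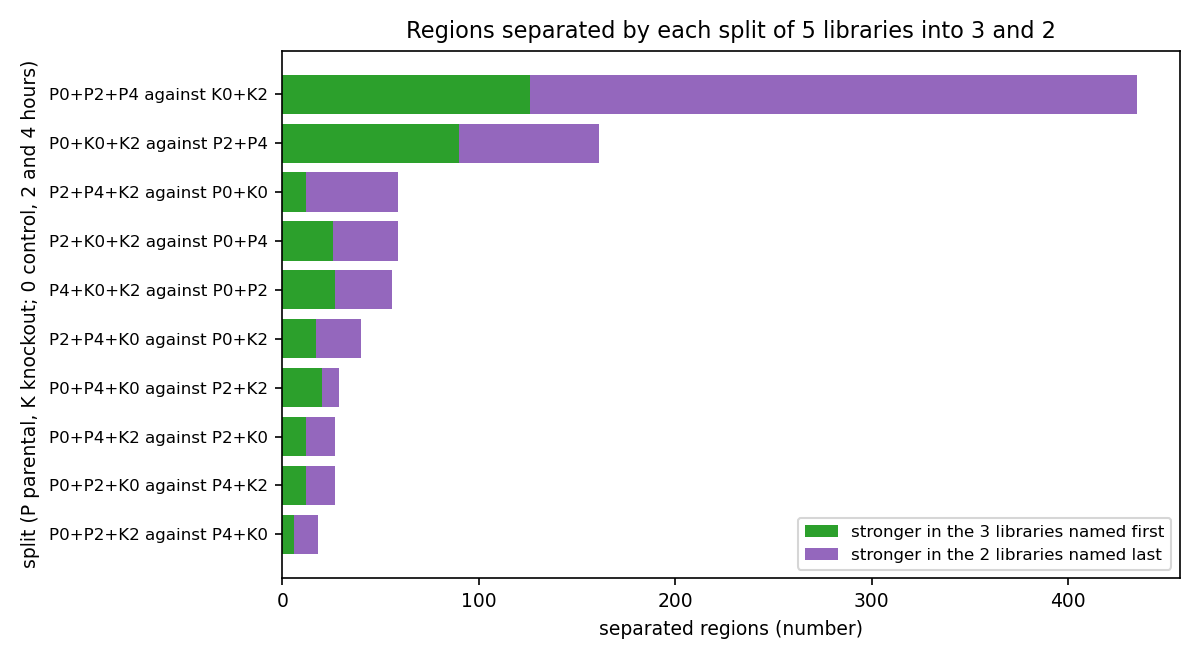
Number of regions separated by each of the 10 splits of 5 libraries into 3 and 2 (P parental, K knockout, 0 control, 2 and 4 hours). The split by genotype separates 435 regions, that of treated parental cells 161, and the others 18 to 59.

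**Figure D5:**
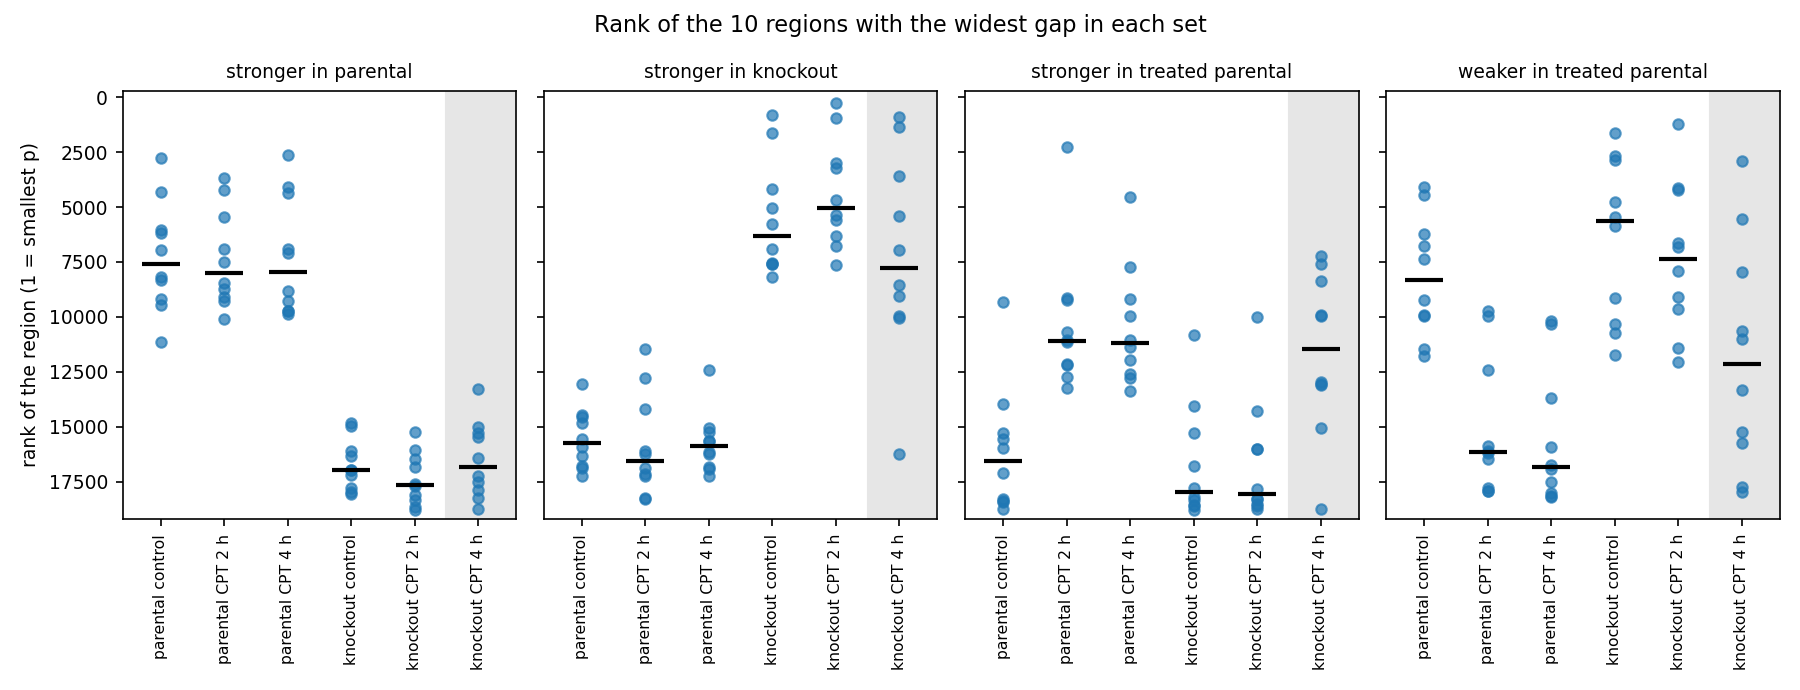
Rank (1 is the smallest p) in each library of the 10 regions with the widest gap in each of 4 sets, with points for regions and bars for medians. The knockout 4 h library, shaded, was not used to choose the regions, and it ranks the knockout-stronger region on chromosome 19 from 16022370 at 1342.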

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

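The tests on the knockout 4 h library, of depth for both region sets, of copy number as a whole cause and of other splits were chosen after the result was seen. The test of weak peaks near the separated regions was set before its result was seen.

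The knockout 4 h list held the most peaks and the fewest strong ones. A complete loss of the strongest marked sites in these cells is argued against. Of the 5000 strongest knockout control peaks, 0 lacked a deposited peak at 4 h, and 99.8% overlapped one of the 30000 strongest. Overlap ignores strength, so a fall in signal at these sites cannot be seen this way. A lower sequencing depth is consistent with the background pileup of 0.168, against 0.506 to 0.715 in the other libraries. A lower yield of the immunoprecipitation and a true fall in signal, at strong or weak sites, stay open and were not tested.

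Regions separated the parental from the knockout libraries. Depth orders the 5 libraries as genotype does, so regions were picked again from parental 4 h and knockout 2 h alone: from parental 2 h to parental control their median shift was 0.327 times (95% interval 0.252 to 0.402) that from parental to knockout control, a like step in background, and with knockout 4 h included the split by genotype separated 218 regions and the split by background 60, which argues against depth as the whole cause and leaves a part of it open. Copy number as the whole cause is argued against, since other regions of like rank within 500 kb of these picked regions shifted between the controls by 0.170 times as much (0.136 to 0.211). It may still contribute: weak peaks near knockout-stronger regions were denser in the knockout than those near parental-stronger regions, by 0.16 on the log2 scale (0.11 to 0.24). Only 1 of the 10 splits of the 5 libraries gave as many regions (435, with 161 in the next), which is too few splits for a share under 5%, parental 2 h alone against the other 4 separated 651 regions and the other single libraries 252 to 367, and an effect of SLFN11 loss and a difference between cultures or clones stay open, both untested.

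Another set separated both treated parental libraries from the other 3. Depth stays open as a cause: parental 2 h and 4 h have the lowest backgrounds of the 5 libraries (0.506 and 0.570). In 1164 regions picked by parental libraries alone, knockout 4 h, with a lower background still, moved from knockout control towards treated parental cells. Its median rank change in weaker regions minus that in stronger regions was 2652 (2073 to 3213). For knockout 2 h this difference was 607 (425 to 932), which is 0.229 times as large (0.157 to 0.368). Its background was 1.02 times that of its control, so a fall in background cannot explain this smaller shift, which rests on 1 library. Of the 10 splits, 2 gave as many regions as the 161 here, and the other was the genotype split with 435. Both splits also follow the order of the background pileup, so these counts cannot tell genotype from depth. The splits are too few for a share under 5%. A response to camptothecin stays open as a hypothesis, with or without a need for SLFN11. A response of knockout cells at 2 h and 4 h would also give these shifts. An untested difference in handling of these libraries stays open too.

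Some changes went one way in one genotype and the opposite way in the other, and these differences were not tested. The covered length of the whole list fell by 34.6 Mb from control to 2 h in knockout cells and rose in parental cells. With matched lists of 30000 peaks both directions turned, with a rise from 36.8 to 37.7 Mb in knockout cells and a fall from 36.3 to 32.1 Mb in parental cells. The window on chromosome 2 from 54830001 gained 3958 bp at 4 h in parental cells and fell in the knockout. Chromosome 10 from 22020001 did likewise, with a parental gain of 3124 bp. Both windows had 0 in knockout 4 h, which cannot be told from an effect of its low background. At 2 h, parental and knockout cells held 2225 and 2269 bp in the chromosome 2 window, and 1206 and 912 bp in the chromosome 10 window. On chromosome 2 from 235160001 parental cover changed by −2908 bp at 4 h, and knockout cover rose. On chromosome 1 from 148640001 the parental change was −379 bp and the knockout change a rise. Peaks on unplaced contigs and alternate haplotypes, which no comparison used, numbered 2530, 2752 and 2826 in parental control, 2 h and 4 h, and 3464, 2920 and 5999 in the knockout libraries.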

How the results depend on the processing

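The window sizes, the 2 h version of the difference between genotypes and all alternatives for the region sets were chosen after seeing the data. No pairing of replicates was possible because the labels give no replicate numbers and each group has 1 library. Parental and knockout libraries were set side by side at each time, and no paired test was run on them. The planned promoter windows, choices of transcript start, gene lists, gene bodies, feature shares and SLFN11 promoter were not run, since an annotation of hg19 was not used here. Windows of 5 and 20 kb left all 7 window results within 1.5 times their main count, as did the 30000 peaks with the highest fold. Settings that take more or fewer peaks change counts of windows by construction, and the cause of the other shifts was not tested. In knockout 4 h the most frequent peaks rest on a pileup of 1 fragment, so its weak sites are uncertain.

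Values follow in one order: parental 2 h and 4 h, knockout 2 h and 4 h, and knockout control against parental control. Windows marked in only one library numbered 55912, 54990, 62159, 79626 and 70278 with all deposited peaks, 3564, 3100, 2483, 9764 and 3154 with the 15000 peaks of smallest p, and 38466, 37002, 34071, 49042 and 36520 with 60000. They numbered 35300, 32061, 26155, 50902 and 28861 with 50 Mb of peaks, 5559, 4643, 4539, 8892 and 4838 at a fold of at least 4, 2878, 2643, 2509, 10109 and 2978 at a −log10 q of at least 5, and 7084, 6293, 6063, 11991 and 6626 with 500 bp covered. Main counts were 15877, 14529, 12217, 22341 and 13758.

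The percentage of control peaks shared was 53.2, 53.9, 50.04, 58.2 and 65.4 with all peaks, 88.6, 89.97, 92.0, 68.4 and 89.9 with 15000, and 57.6, 58.5, 62.1, 47.8 and 60.0 with 60000. It was 83.6, 83.0, 85.4, 55.3 and 84.9 at a fold of at least 4, 86.1, 87.7, 94.3, 36.1 and 92.2 at a −log10 q of at least 5, and 67.8, 70.7, 75.1, 55.3 and 73.1 when 50% of the peak had to be covered. Without knockout 4 h, which stayed within its interval, it was 67.4, 69.5, 72.2 and 70.1 with the 30000 peaks of highest fold and 64.9, 64.6, 65.3 and 63.1 with 50 Mb of peaks. Knockout 4 h against its control was the lowest in each setting with a matched number of peaks, and with all peaks the lowest was knockout 2 h.

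Covered length in Mb, in the order parental control, 2 h and 4 h and knockout control, 2 h and 4 h, was 36.3, 32.1, 34.0, 36.8, 37.7 and 26.5 for the matched lists. It was 123, 125, 127, 193, 159 and 190 with all peaks on these chromosomes, 22.5, 20.4, 21.6, 22.3, 22.7 and 15.7 with 15000 peaks, 55.7, 50.2, 52.6, 58.1, 59.4 and 40.5 with 60000, and 32.7, 29.1, 30.9, 32.5, 33.5 and 26.9 with the 30000 of highest fold. It was 15.9, 15.6, 15.5, 16.3, 16.9 and 9.86 at a fold of at least 4, 21.0, 17.9, 19.0, 21.6, 22.99 and 6.90 at a −log10 q of at least 5, and 49.9989, 49.9998, 49.9993, 49.9998, 50 and 49.9999 with 50 Mb of peaks, as that setting fixes it.

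Windows where the signed parental or knockout change at 4 h was greater by 1000 bp numbered 27910 and 20935 with all peaks and 3518 and 694 with 15000 peaks. They numbered 11534 and 4868 with 60000, and 3346 and 781 at a fold of at least 4. The knockout count moved to 6793 with 50 Mb of peaks and to 388 at a −log10 q of at least 5, while the parental count stayed within 1.5 times. The parental count was the larger in these settings, and at 2 h the order turned, with 2213 and 4440. The order at 4 h cannot be told from an effect of the low background of knockout 4 h.

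Regions separated by genotype and by treated parental cells numbered 894 and 541 at a rank gap of 2000, 113 and 19 at a gap of 5000, and 103 and 25 with regions from the 10000 strongest peaks. With ranks by fold the treated parental set grew to 420 and the genotype set to 515. With knockout 4 h included, 3 libraries against 3, the genotype set held 218 regions, and 1 of 10 splits gave as many. In each of these settings the genotype set was larger than the treated parental set where both were run, and both exceeded the third largest split, which held 240, 6, 10 and 212 regions in that order of settings.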

Other observations

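The values in this part were chosen after the data were seen and were not tested. Peaks of the matched lists at most 10 kb apart were joined into clusters, and the 100 with the longest cover were compared between libraries. Clusters in the top 100 of all 6 libraries lay on chromosome 6 from 26156340 to 26252341, with 32.2 kb covered in parental control, on chromosome 17 from 78717001 to 78765060, with 21.99 kb, on chromosome X from 114959715 to 115005160, with 21.7 kb, and on chromosome 6 from 135529069 to 135598604, with 20.1 kb. The chromosome X cluster was also the largest of knockout 4 h, with 22.1 kb. On chromosome 3, a cluster from 45873363 to 45971526 led the knockout 2 h list with 36.1 kb and was second in knockout control, with 27.9 kb. It was in the top 100 of 5 libraries, so it was not particular to the knockout. Another on chromosome 8 from 86726474 to 86840854 led parental 2 h with 29.6 kb and was in the top 100 of 2 libraries. Of the top 100 of knockout control, 72 were in that of knockout 2 h, 66 in that of parental control and 36 in that of knockout 4 h.

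On chromosome 1, the largest cluster of parental 4 h ran from 228744113 to 228782539 with 33.8 kb covered, and the matching cluster of knockout 4 h had 21.1 kb. Reads shared between repeat copies, as in the 5S ribosomal RNA array, were not checked at this place. The widest single peak of parental 4 h lay inside it, from 228759690 to 228772047, with a fold of 1.35. Regions separated by genotype lay on all 23 chromosomes, and their share was highest on chromosome 3, where 45 regions were stronger in the knockout and 16 in parental cells, 5.49% of 1112, against 2.31% over all chromosomes. Near 18 Mb of that chromosome lay the region at 18426648 that was stronger in the knockout and the one at 17980562 that fell in treated parental cells.

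The strongest peak of all 6 lists, on chromosome 2 from 33141145, kept its p in the knockout 4 h library, which has a low background. Its −log10 p was 117 there and between 118 and 123 in the other libraries, while that of the second peak was 45.2 against 80.1 to 99.3. The ratio of the first to the second was 2.60 in knockout 4 h and 1.202 to 1.47 elsewhere. The cause of this difference was not tested, and a mapping artifact at this place was not checked.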
